A study of Mus musculus with 9 samples.

How the data were processed

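Gene expression was measured in sorted mouse brain cells on 9 Agilent arrays read in 1 colour, 3 in each of 3 groups. The cells were sorted by fluorescence from the dissected tissue of mice that carry a reporter gene. In Sox2-GFP mice green fluorescent protein is made under the promoter of Sox2, a transcription factor of neural stem cells. In DCX-DsRed mice a red fluorescent protein is made under the promoter of Dcx, a gene of newborn neurons. The groups were Sox2-GFP cells of the hippocampus, DCX-DsRed cells of the hippocampus and Sox2-GFP cells of the subventricular zone (SVZ), the stem cell region along the lateral ventricle. Per the labels' protocols, tissue from 10 dissections of mice aged 6 to 8 weeks was pooled for each experiment, and RNA of 1000 cells was amplified with a commercial small-sample protocol and labelled with Cy3. Groups and replicate letters (A, B and C) were taken from the sample titles. The labels do not say whether the replicates of a group came from separate pools of animals, so p-values measure only the spread between these samples, which may be technical.

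Each deposited file was the scanner output of 1 array. Per the file headers, spot intensities had been extracted with Agilent Feature Extraction 9.5.1.1, which subtracted the local background, removed spatial trends and put a surrogate in place of values under the noise to give the processed signal. That intensity was not normalized between arrays. The deposited files also held the raw mean intensity of each spot, the median intensity of its local background, and other columns of 0 and 1 flags for spots well above background, saturated spots and outlier spots, per the file headers. The submitters' processing notes name limma, with no version or step. The file of hippocampus DCX-DsRed replicate A had been saved again by a spreadsheet program, which altered 47 gene symbols and rounded signals. Gene names were therefore taken from an intact file of the same design.

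Control spots were left out, and 43379 spots of 41174 probes remained. Spots with an outlier flag were left out, the spots of a probe were averaged, and 464 probes with no unflagged spot on at least 1 array were dropped, leaving 40710. Values were log2 of the processed signal minus the array's 75th percentile over all non-control probes. A value of 0 is therefore the array's own 75th percentile, and a difference of 1 is a factor of 2. From the files' accession column, 22664 probes were named through a RefSeq gene table (assembly GRCm38.p6, used for names only), which changed 5087 symbols. A further 3072 probes carried an older symbol of exactly 1 gene in that table and were renamed, 14692 kept the name in the file, and 282 had no name. The build of the probe coordinates was not given in the sources used here, so no coordinates are reported. Probes well above background on at least 3 of the 9 arrays were kept, and the probe with the highest mean signal stood for its gene, which gave 24897 genes. Where called genes had several probes, all other probes had the same sign for 240 of 263 genes in the hippocampal comparison and for 25 of 26 in the comparison of regions.

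Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, on all 9 arrays with 6 residual degrees of freedom, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The comparisons were hippocampus Sox2-GFP minus hippocampus DCX-DsRed, and SVZ Sox2-GFP minus hippocampus Sox2-GFP. A gene whose probe was not well above background on any array of the dimmer group has only a bound. Its fold is then given as "at least", computed from the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Such a bound holds for this processing only. Each named gene with a bound had a smaller difference than it in some alternative listed below. Folds of other genes come from the difference of means. Of the lists of genes, 32 were fixed before the data were examined, and 31 were tested with camera with a preset correlation of 0.01, adjusted over the 31. The list of the 2 sorting reporters was not tested. Camera with a correlation estimated for each list, and the directional test of fry, were run beside it. Some genes stand in more than 1 list, such as Igf2 and Id4. Counts "adjusted over the list alone" come from adjusting the gene p-values within each list.

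Genes are named by a rule fixed at the same time. Sox2, Dcx and Igf2 are given in both comparisons. For each comparison, the 10 genes with the largest difference in each direction are named if the adjusted p is under 0.05, the groups do not overlap, all 3 arrays of the higher group were well above background, and the symbol is not a clone or model name. For each list, up to 3 called members with the largest difference are named, or, where none was called, the member with the smallest p, with its value. A few genes that the rule would name are not reported here. Of the called genes, 237 in the hippocampal comparison and 33 in the comparison of regions had clone or model names and are not named. Genes without a usable probe under their name are not analysed here.

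The arrays lay on 3 slides. Slide 1 held DCX-DsRed A and B and SVZ A, slide 2 held hippocampus Sox2-GFP A and B, and slide 3 held hippocampus Sox2-GFP C, DCX-DsRed C and SVZ B and C. Values with slide as a block, and differences within slide 3 (1 array of each hippocampal group and 2 of the SVZ, with no test), stand beside the results. Slide 2 held no other group, so with slide as a block hippocampus Sox2-GFP A and B add nothing to a difference between groups, which then rests on replicate C. Between 80.3% and 88.3% of probes were well above background per array, and no probe was saturated. The precision is limited by the number of arrays. The tests were checked on simulated data with the spread of these arrays. In the hippocampal comparison, of 50 simulated genes per size, 0 with a log2 change of 1, 5 with 2, 29 with 4 and 43 with 6 were called, along with 3 of 24676 unchanged genes. In the comparison of regions these counts were 0, 8, 31 and 43, along with 6 of 24676 unchanged genes. A simulated list shift of 2 was called in both, with 1 of the 30 other lists called in the first and 0 in the second. The simulated genes varied independently, while correlations estimated within the real lists reached 0.41 (astrocyte genes). The list tests were thus not checked for such correlation. Simulated changes of 4-fold (log2 of 2) were therefore mostly not called with 3 arrays per group.

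The alternatives covered quantile normalization, normexp background correction with an offset of 50, another set of probes for the percentile, other filters on dim probes, a floor on dim values, means over probes, every probe as a feature, other fits (6 arrays, intensity trend, array weights, slide and replicate letter as blocks), each array left out, stricter thresholds and other list tests. Gene names from accessions only was an alternative chosen after seeing the data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.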

Results

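Messenger RNA levels were compared between cells of the adult mouse brain sorted by a reporter meant for neural stem cells (Sox2-GFP) or by one meant for newborn neurons (DCX-DsRed). Each of the 3 groups (Sox2-GFP cells of the hippocampus, DCX-DsRed cells of the hippocampus and Sox2-GFP cells of the SVZ) was measured on 3 arrays. Each array carried amplified RNA of 1000 cells. Values are log2 signal relative to the array's 75th percentile, given as mean ± SD with n = 3, and differences carry their standard error (SE). Between 80.3% and 88.3% of probes per array were well above background. The series title names IGF2, insulin-like growth factor 2, as a regulator of neurogenesis in the adult hippocampus, and the design sets the reporters against each other in the hippocampus and the regions against each other for Sox2-GFP.

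The mRNAs of the genes behind the reporters did not follow the sort. Sox2 was lower on each hippocampus Sox2-GFP array than on each DCX-DsRed array, and Dcx overlapped between these groups. Sox2 stood at 0.33 ± 1.08 in hippocampus Sox2-GFP cells, 1.60 ± 0.23 in DCX-DsRed cells and 1.78 ± 0.73 in SVZ Sox2-GFP cells. Dcx stood at -1.26 ± 1.41, -0.24 ± 1.36 and 1.11 ± 2.998 in the same order. On hippocampus Sox2-GFP replicates A, B and C, Sox2 read 0.96, 0.94 and -0.92 and Dcx -0.17, -0.75 and -2.85. On DCX-DsRed replicates A, B and C, Sox2 read 1.33, 1.74 and 1.72 and Dcx -1.26, -0.76 and 1.30. On SVZ replicates A, B and C, Sox2 read 0.94, 2.09 and 2.30 and Dcx 2.60, 3.07 and -2.34. Between hippocampus Sox2-GFP and DCX-DsRed cells, Sox2 differed by -1.27 (SE 0.59, adjusted p = 0.328) and Dcx by -1.02 (SE 1.46, adjusted p = 0.778). With slide as a block, where hippocampus Sox2-GFP rests on replicate C, the difference of Sox2 was -2.99 (SE 0.48, adjusted p = 0.0232; 0.0232 to 0.5645 over 21 alternatives). Without replicate C it was -0.65 (adjusted p = 0.5645), and that of Dcx was -0.22 (adjusted p = 0.966). The reporters therefore do not check the labels of these samples.

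Hippocampus Sox2-GFP replicate C stood apart from the other arrays. Across genes, which are not independent replicates, it correlated at r = 0.816 with replicate A and 0.7835 with replicate B, while A and B, on 1 slide, correlated at 0.919. The first principal component, with 29.0% of the variance, placed it at -246.8 against -34.2 and -24.4 for replicates A and B. The astrocyte list below had a median 2.75 log2 units lower in replicate C than in the mean of A and B, and the choroid plexus list was 1.47 higher. Slide 2 held only hippocampus Sox2-GFP A and B, so in the values with slide as a block and within slide 3 below this group rests on replicate C.

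**Figure D1:**
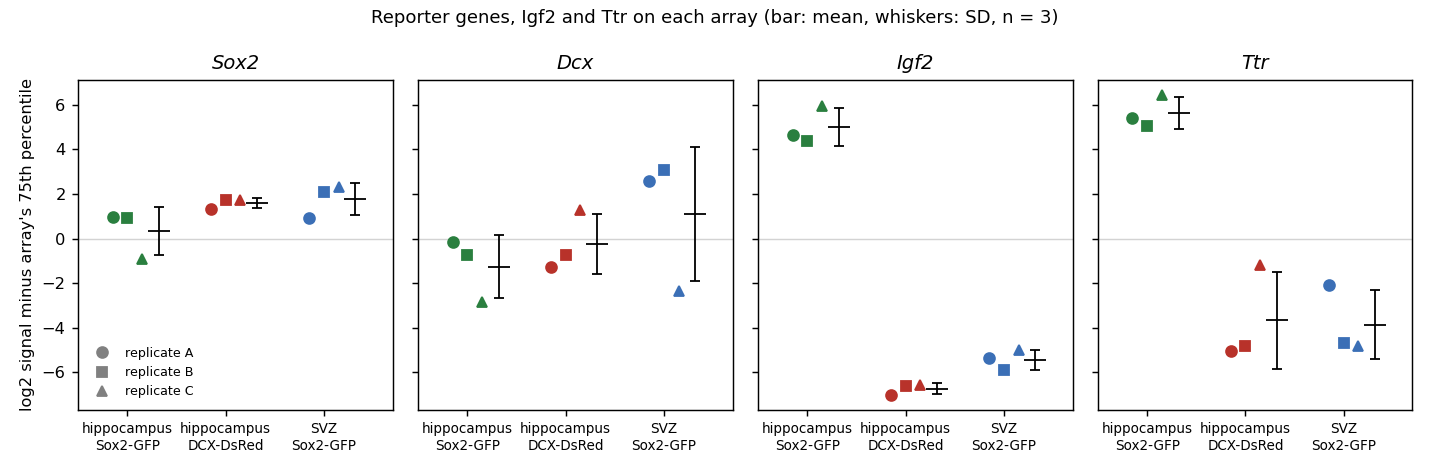
Log2 signal minus the array's 75th percentile (vertical axis) of Sox2, Dcx, Igf2 and Ttr on each array of the 3 groups (horizontal axis), with marker shape for the replicate letter and bar and whiskers for mean and SD of 3 arrays. The groups overlap for Dcx, while Igf2 and Ttr lie above 4 on the hippocampus Sox2-GFP arrays and below 0 on the 6 others.

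The first comparison set Sox2-GFP cells of the hippocampus against DCX-DsRed cells of the same region. Igf2, the growth factor of the series title, had the largest named difference. It stood at 4.997 ± 0.84 in Sox2-GFP cells and was not well above background on any DCX-DsRed array, so it was at least 1978-fold higher in this processing (adjusted p = 0.000117). Igf2 differed by as little as 6.44 (log2) over its alternatives, less than that bound. Its measured log2 difference, with the DCX-DsRed side at -6.74 and not well above background, was 11.73, 12.65 with slide as a block and 12.53 within slide 3, none of which sets its size. Genes of the choroid plexus, the tissue that secretes cerebrospinal fluid, and of ciliated ependymal cells were higher in the Sox2-GFP cells as lists, and genes of myelin-forming oligodendrocytes in the DCX-DsRed cells. None of these 3 lists passed with an estimated correlation (adjusted p = 0.122 for each). In all, 790 of 24897 genes passed an adjusted p of 0.05, 434 higher and 356 lower in Sox2-GFP cells, and 128 of them have only a bound.

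Among the 10 genes with the largest rises in hippocampus Sox2-GFP cells, Ttr, Tmem72 and Otx2 were members of the choroid plexus list. Ttr, which encodes the thyroid hormone carrier transthyretin, was 635-fold higher (5.64 ± 0.73 against -3.67 ± 2.17, adjusted p = 0.00669). Tmem72, a transmembrane protein gene, was 665-fold higher (SE 1.34 on a log2 difference of 9.38, adjusted p = 0.0118). Otx2, a homeobox transcription factor, was 262.5-fold higher (log2 difference 8.04, SE 1.103, adjusted p = 0.00989). Cldn1, which encodes the tight junction protein claudin 1, was 147.5-fold higher (adjusted p = 0.0036). Ecrg4, a secreted peptide precursor gene, was 444-fold higher (adjusted p = 0.0155). Tmem72, Otx2, Cldn1 and Ecrg4 were well above background on 1 of 3 DCX-DsRed arrays and Ttr on 2. Sulf1, a heparan sulfate sulfatase, was at least 160-fold higher (adjusted p = 0.00423), and Cdkl4, a protein kinase gene, at least 86.8-fold (adjusted p = 0.00355). Their smallest log2 differences over the alternatives were 4.98 and 4.52, less than these bounds. Slc2a12, a glucose transporter gene, was 189-fold higher (adjusted p = 0.0311), and Lrriq1 149-fold (adjusted p = 0.00856), each well above background on 1 DCX-DsRed array. Some of these folds moved by over 1.5 times without 1 array. Leaving out DCX-DsRed replicate A gave 394-fold for Ttr, 417-fold for Tmem72 and 371-fold for Slc2a12, the last 2 not called. Leaving out DCX-DsRed B gave 1961-fold for Tmem72, 148-fold for Otx2, 793-fold for Ecrg4 and 97.7-fold for Lrriq1. Leaving out DCX-DsRed C gave 1512-fold for Ttr, 360.1-fold for Tmem72, 687-fold for Otx2, 272-fold for Ecrg4 (not called) and 295-fold for Lrriq1. Without hippocampus Sox2-GFP B, Cldn1 was 260.1-fold higher, and without C Otx2 was 174-fold, Ecrg4 256-fold and Slc2a12 120.5-fold higher (the last not called).

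Of 14 measured choroid plexus genes, 11 rose in hippocampus Sox2-GFP cells and 0 fell (13 rose adjusted over the list alone). The mean difference was 4.83 ± 2.67 (SD over genes), and the list passed camera (adjusted p = 2.76e-17), but not with an estimated correlation (adjusted p = 0.122). With slide as a block the mean was 6.13, and within slide 3 it was 5.995. Tmem72, Ttr and Otx2 had the largest differences of this list, and Igf2 was not in it. The list is short, so this does not set Igf2 apart from the choroid plexus pattern. Of 19 ependymal genes, 8 rose and 0 fell (10 adjusted over the list alone), with a mean of 3.28 (camera adjusted p = 1.13e-11; 0.122 with an estimated correlation). The ependymal mean was 2.78 with slide as a block and 2.93 within slide 3. Foxj1, the master transcription factor of motile cilia, was 33.5-fold higher (1.58 ± 0.29 against -3.48 ± 1.41, adjusted p = 0.0115; 19.03-fold without DCX-DsRed replicate C). Enkur, a sperm and cilium protein gene, was at least 54.7-fold higher (adjusted p = 0.0135), and Pifo, a primary cilium gene, was 119-fold higher (adjusted p = 0.0218) and well above background on 1 DCX-DsRed array. The smallest log2 difference of Enkur over its alternatives was 3.95, less than its bound.

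The BMP and TGF beta, IGF and Notch lists had smaller means. Of 20 BMP and TGF beta pathway genes, 4 rose (8 rose and 1 fell adjusted over the list alone), with a mean of 1.17 (camera adjusted p = 0.00233; 0.122 with an estimated correlation). Its mean was 1.16 with slide as a block and 1.39 within slide 3. Id4, an inhibitor of differentiation that BMP signals induce, was 20.1-fold higher (adjusted p = 0.0073), the ligand gene Bmp7 8.5-fold (adjusted p = 0.04; 5.47-fold and not called without hippocampus Sox2-GFP replicate C) and the receptor gene Tgfbr2 4.26-fold (adjusted p = 0.0424). Of 19 IGF system genes, 2 rose (2 adjusted over the list alone), with a mean of 1.097 and a median of 0.22 (camera adjusted p = 0.0483; 0.212 with an estimated correlation). The mean of that list was 0.65 with slide as a block and 0.80 within slide 3. Beside Igf2, Igfbp7, which encodes a secreted IGF-binding protein, was 29.4-fold higher (log2 difference 4.88, SE 0.86, adjusted p = 0.0256; 19.05-fold and not called without DCX-DsRed replicate A). No member of the 19 Notch pathway genes passed, also adjusted over the list alone, although their mean of 0.74 passed camera (adjusted p = 0.0376; 0.465 with an estimated correlation). The Notch mean was -0.71 with slide as a block and -0.61 within slide 3, 0.42 without hippocampus Sox2-GFP replicate B (adjusted p = 0.151) and 1.23 without C (adjusted p = 0.00745). Hes1, the Notch target with the smallest p, differed by 4.31 (SE 1.14, adjusted p = 0.0927).

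Of 25 astrocyte genes, 3 rose in hippocampus Sox2-GFP cells and 0 fell (7 adjusted over the list alone), with a mean of 1.21 (camera adjusted p = 0.000283; 0.465 with an estimated correlation). The direction of this list changed with the slide: its mean was -0.87 with slide as a block and -0.82 within slide 3, which holds hippocampus Sox2-GFP replicate C. Without replicate C it was 2.04 (adjusted p = 1.52e-12, the lowest over its alternatives, which reached 0.465), and without B 0.76 (adjusted p = 0.0105). Clu, which encodes the secreted chaperone clusterin, was 19.2-fold higher (4.23 ± 0.43 against -0.03 ± 1.12, adjusted p = 0.0122; 12.6-fold without DCX-DsRed replicate B), Slc7a10, a serine transporter gene, 9.21-fold (adjusted p = 0.0115) and Sdc4, a syndecan gene, 6.2-fold (adjusted p = 0.0467; 3.92-fold without hippocampus Sox2-GFP replicate C). Of 27 neural stem and progenitor genes, only Id4 passed (3 rose and 1 fell adjusted over the list alone), and the list did not pass camera (mean 0.39, adjusted p = 0.0835). Without hippocampus Sox2-GFP replicate C that mean was 0.94 (adjusted p = 0.00285), and with slide as a block it was -0.70 (adjusted p = 0.662).

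Further lists passed camera with few called members. Eno1, which encodes the glycolytic enzyme enolase 1, was the only riser of 17 glycolysis genes (6.14-fold, adjusted p = 0.0266; 7 rose adjusted over the list alone), and the list mean was 1.06 (camera adjusted p = 0.000288; 0.155 with an estimated correlation). Of 18 fatty acid oxidation genes, 2 rose (3 adjusted over the list alone), with a mean of 0.90 (camera adjusted p = 0.0081; 0.212 with an estimated correlation). Etfa, which carries electrons from this pathway to the respiratory chain, was 15.7-fold higher (1.40 ± 0.18 against -2.58 ± 0.24, adjusted p = 0.00223), and Acaa2, a mitochondrial thiolase gene, 9.84-fold (adjusted p = 0.0335). Of 22 endothelial and mural genes, 3 rose (4 adjusted over the list alone), with a mean of 1.18 (camera adjusted p = 0.0081; 0.465 with an estimated correlation). The angiopoietin receptor gene Tek was at least 13.1-fold higher (adjusted p = 0.0138), Vtn 13.96-fold (adjusted p = 0.0276) and Bsg 8.37-fold (adjusted p = 0.0286). The smallest log2 difference of Tek over its alternatives was 1.74, less than its bound. Vtn, the vitronectin gene, marks pericytes. Of 17 meningeal fibroblast genes, 2 rose (2 adjusted over the list alone), with a mean of 0.85 (camera adjusted p = 0.0445; 0.465 with an estimated correlation). They were Ogn (12.2-fold, adjusted p = 0.0243) and Zic1 (8.54-fold, adjusted p = 0.0328), the latter well above background on 2 DCX-DsRed arrays. Of 26 dissociation and stress response genes, Ccn1 rose (7.67-fold, adjusted p = 0.0203; 4 rose adjusted over the list alone), with a list mean of 0.64 (camera adjusted p = 0.0445; 0.465 with an estimated correlation). With slide as a block the means were 0.74 for glycolysis, 0.97 for fatty acid oxidation, 0.45 for endothelial and mural, 1.45 for meningeal and 0.73 for stress genes. Within slide 3 they were 0.55, 1.14, 0.69, 1.51 and 0.85. Acaa2 was 15.65-fold higher without DCX-DsRed replicate A, Vtn 22.3-fold without hippocampus Sox2-GFP A, and Ogn and Zic1 7.46-fold and 5.47-fold without hippocampus Sox2-GFP C.

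In the other direction, 11 of 18 genes of myelinating oligodendrocytes were lower in hippocampus Sox2-GFP than in DCX-DsRed cells and 0 were higher (17 lower and 1 higher adjusted over the list alone). The mean difference was -4.08 ± 2.22 (SD over genes; camera adjusted p = 6.16e-15; 0.122 with an estimated correlation), -5.75 with slide as a block and -5.97 within slide 3. Without hippocampus Sox2-GFP replicate C, which had the lowest myelin values, the mean was -3.25. Ermn, a cytoskeletal protein gene of oligodendrocytes, was 504-fold lower in the Sox2-GFP cells (adjusted p = 0.00462) and well above background on 2 of their arrays. Without hippocampus Sox2-GFP replicate C it was 199-fold lower (adjusted p = 0.000911; 1.9e-05 to 0.0269 over 20 alternatives), and without B 885-fold. Mog, which encodes myelin oligodendrocyte glycoprotein, was 46.9-fold lower (-1.19 ± 1.86 against 4.37 ± 0.45, adjusted p = 0.0208; 22.4-fold without hippocampus Sox2-GFP C and 72.6-fold without A), and the gap junction gene Gjb1 28.9-fold (adjusted p = 0.00325). Of 17 oligodendrocyte precursor genes only Sox8 passed (6.93-fold lower, adjusted p = 0.0494, 10.8-fold without hippocampus Sox2-GFP B and 4.57-fold, not called, without C; 3 lower and 1 higher adjusted over the list alone), and the list did not pass camera (mean -1.01, adjusted p = 0.239).

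Other genes with the largest falls in the Sox2-GFP cells stood in none of the oligodendrocyte lists. Those lists are short, so this does not set the genes apart from the myelin pattern. Anln, which encodes the actin-binding protein anillin, was 430-fold lower (-4.37 ± 0.19 against 4.38 ± 0.31, adjusted p = 0.000175). Apod, the apolipoprotein D gene, was 70.4-fold lower (adjusted p = 0.0164), and Gatm, an enzyme of creatine synthesis, 67.7-fold (adjusted p = 0.002). S1pr5, a sphingosine 1-phosphate receptor gene, was 153-fold lower (adjusted p = 0.0427) and Carns1, the carnosine synthase gene, 89.5-fold (adjusted p = 0.035), each well above background on 1 Sox2-GFP array. Cyp27a1, which encodes sterol 27-hydroxylase, was at least 68.6-fold lower (adjusted p = 0.00778). Its smallest log2 difference over the alternatives was -3.78, less than this bound. Speer4a (250-fold, adjusted p = 0.0121), Speer4b (223-fold, adjusted p = 0.00535) and Speer8-ps1 (129-fold, adjusted p = 0.00765) were also lower. These belong to 1 family of near-identical genes and a pseudogene, so their probes may not tell them apart, and Speer8-ps1 was well above background on 1 Sox2-GFP array. The folds in this direction also moved by over 1.5 times with 1 hippocampus Sox2-GFP array left out. Without replicate A they were 497 for S1pr5, 177.5 for Carns1, 624 for Speer4a, 498 for Speer4b and 229.7 for Speer8-ps1. Without B they were 158 for Apod, 85.1 for S1pr5 (not called) and 77.2 for Speer8-ps1. Without C they were 32.4 for Apod, 84.3 for S1pr5 and 55.75 for Carns1 (both not called), 112 for Speer4a and 122 for Speer4b.

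The immature neuron, axon guidance and migration, and histone and chromatin lists were lower in the Sox2-GFP cells by smaller amounts. Of 27 immature neuron genes, Stmn1 fell (6 fell and 1 rose adjusted over the list alone), with a list mean of -1.07 (camera adjusted p = 0.0081; 0.469 with an estimated correlation). The immature neuron mean was -1.82 with slide as a block and -2.22 within slide 3, which rest on hippocampus Sox2-GFP replicate C, and -0.64 without that array (adjusted p = 0.0109). Stmn1, which encodes the microtubule regulator stathmin, differed by -4.46 (SE 0.90, adjusted p = 0.0395), a 22.05-fold fall that was 38.4-fold without replicate B and 10.5-fold without C. Of 28 axon guidance and migration genes, Efnb3, which encodes the guidance ligand ephrin B3, fell (54.3-fold, adjusted p = 0.00858, 86.65-fold without hippocampus Sox2-GFP B and 34.6-fold without C; 2 fell and 1 rose adjusted over the list alone). The mean of the list was -0.64 (camera adjusted p = 0.0483; 0.465 with an estimated correlation), -1.04 with slide as a block and -1.19 within slide 3, but -0.35 without replicate C (adjusted p = 0.0965). None of 20 histone and chromatin regulators passed (3 fell adjusted over the list alone), and their mean was -0.58 (camera adjusted p = 0.0402; 0.216 with an estimated correlation), -1.22 with slide as a block and -1.33 within slide 3, but -0.34 without replicate C (adjusted p = 0.0208). These 3 lists were lower in hippocampus Sox2-GFP replicate C than in the mean of A and B, with medians of -0.99, -0.98 and -0.17.

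The remaining lists did not pass camera between hippocampus Sox2-GFP and DCX-DsRed cells. Single members passed in some of them. Dlg4, a postsynaptic scaffold gene, was 6.88-fold higher (adjusted p = 0.012; 1 of 24 mature neuron and synapse genes also adjusted over the list alone, camera adjusted p = 0.394). Igf2 and Peg3 (3.81-fold, adjusted p = 0.0449) were the 2 risers of 25 imprinted genes (5 adjusted over the list alone, camera adjusted p = 0.0835), whose mean was 0.69 and median -0.11. Bad, a pro-apoptotic gene, was 5.998-fold higher (adjusted p = 0.0115; 1 of 19 apoptosis genes also adjusted over the list alone, camera adjusted p = 0.83), in a list with a mean of 0.02, a median of -0.12 and a downward camera direction. Wnt3 (11.45-fold, adjusted p = 0.0178; 7.52-fold without hippocampus Sox2-GFP C) fell among 21 Wnt pathway genes (4 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.0513). Hhip (9.81-fold, adjusted p = 0.0178), well above background on 2 Sox2-GFP arrays, fell among 12 hedgehog pathway genes (2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.71). Meis1 (13.05-fold, adjusted p = 0.00802) fell among 17 ventral telencephalic transcription factors and Scd2 (3.65-fold, adjusted p = 0.0311) among 16 fatty acid synthesis genes, each also adjusted over the list alone (camera adjusted p = 0.273 and 0.61).

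No member passed in 7 further lists of the hippocampal comparison, for which limma gave 4212 genes at an unadjusted p under 0.05 over all genes. The members with the smallest p were Reln of 10 GABAergic neuron genes (-0.84, adjusted p = 0.344), Cd14 of 20 microglia genes (-0.85, adjusted p = 0.295), Alas2 of 7 blood cell genes (1.98, adjusted p = 0.0583) and Rrm2 of 22 S phase genes (at least 2.97-fold higher, adjusted p = 0.0673; well above background on 2 of 3 Sox2-GFP arrays). Mki67 of 23 G2 and M phase genes (-1.78, adjusted p = 0.11) and Prox1 of 17 dorsal telencephalic transcription factors (-2.17, adjusted p = 0.0559) had the smallest p of their lists, and the remaining list was the 18 cholesterol synthesis genes. The smallest log2 difference of Rrm2 over its alternatives was 0.52, less than its bound. Adjusted over the list alone, 1 blood cell gene and 2 S phase genes rose, 1 dorsal factor fell, and 0 passed in the 4 other lists. The camera adjusted p-values, in the order of the lists named, were 0.36, 0.25, 0.778, 0.71, 0.36, 0.734 and 0.795.

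Of the 51 called genes named for the hippocampal comparison, 16 kept an adjusted p under 0.05 in each alternative that tested them, Igf2, Ttr, Otx2, Cldn1, Sulf1, Cdkl4, Clu, Etfa, Anln, Ermn, Gatm, Gjb1, Efnb3, Meis1, Cyp27a1 and Speer4b. Sulf1 and Ermn were tested in 20 alternatives and the others of these genes in 21. When slide was a block, 43 of the 51 kept an adjusted p under 0.05, all 51 kept their direction, and Lrriq1, S1pr5, Speer8-ps1, Id4, Tek, Foxj1, Tgfbr2 and Ccn1 did not pass (0.0507 to 0.107). For 31 genes the call ended when 1 array was left out, with adjusted p from 0.05 to 0.157, and 7 of these (Pifo, Slc2a12, Igfbp7, Peg3, Bmp7, Tgfbr2 and Scd2) lost it whichever of the 6 arrays was left out. Of the 45 of these genes with a fold and not a bound, 28 had it moved by over 1.5 times without 1 array, up to 3.25 times for S1pr5 without hippocampus Sox2-GFP A. Over all alternatives some moved further. The log2 difference was as small as 4.39 for Slc2a12 and 4.21 for Lrriq1, against 7.56 and 7.22 in the main fit. The count of 790 was 330, 431 and 773 without hippocampus Sox2-GFP replicates A, B and C, and 251, 287 and 375 without DCX-DsRed replicates A, B and C. Of the 15 called lists, 8 lost their call without 1 array (camera adjusted p from 0.0503 to 0.323): endothelial and mural genes without hippocampus Sox2-GFP B, immature neuron genes without DCX-DsRed C (0.0729), and the meningeal, IGF, Notch, axon guidance, histone and stress lists without at least 2 of the arrays in turn. Only 5 of the 15 passed with slide as a block, the choroid plexus, myelin, ependymal, meningeal, and BMP and TGF beta lists.

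**Figure D2:**
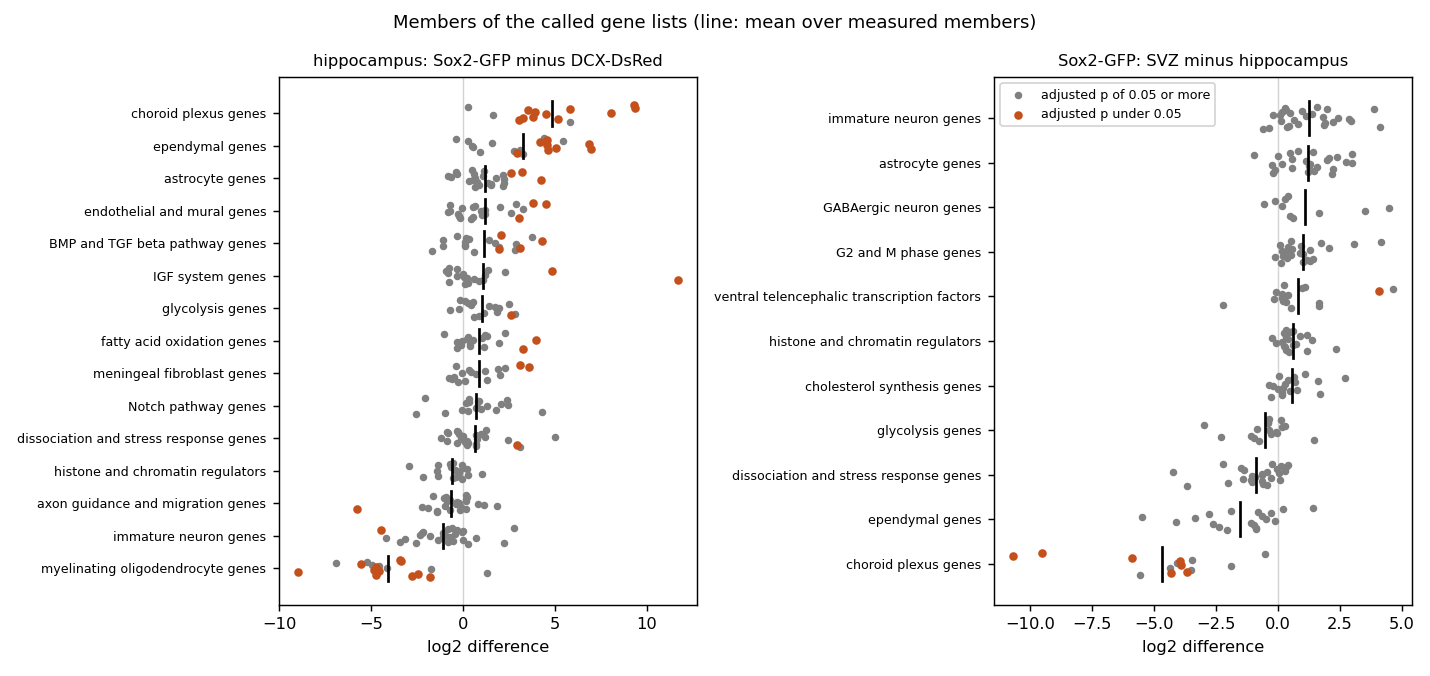
Log2 difference (horizontal axis) of each measured member of the gene lists that passed camera with the preset correlation, for hippocampus Sox2-GFP minus DCX-DsRed (left) and SVZ minus hippocampus Sox2-GFP (right), with the list mean as a black line and genes with an adjusted p under 0.05 in orange. Choroid plexus genes have the largest mean on the left (4.83) and the lowest on the right (-4.67), and myelin genes the lowest on the left (-4.08).

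The second comparison set Sox2-GFP cells of the SVZ against those of the hippocampus. Igf2, Tmem72, Ttr and Sulf1, among the 10 largest rises of the first comparison, were among the 10 largest falls here. Igf2 was 1375-fold lower in SVZ cells (-5.43 ± 0.45 against 4.997 ± 0.84, adjusted p = 0.000306) and well above background on 2 of 3 SVZ arrays, a log2 difference of -10.43 (-11.37 with slide as a block and -11.43 within slide 3). Over its 21 alternatives this difference was as small as -7.96. Choroid plexus genes were lower in the SVZ as a list, and G2 and M phase genes and immature neuron genes were higher there as lists, with no called member. With an estimated correlation none of the 3 passed (adjusted p = 0.146, 0.37 and 0.37). On SVZ replicate C the immature neuron mean of -1.37 lay below those of hippocampus Sox2-GFP A and B (-1.06 and -1.27), and the G2 and M mean of -1.26 was close to theirs (-1.34 and -1.56). Of 24897 genes, 99 passed, 11 higher and 88 lower in the SVZ, and 28 of them have only a bound. The reporter gene Sox2 differed by 1.45 (SE 0.59, adjusted p = 0.432; 2.94 with slide as a block, adjusted p = 0.0193, but 0.83 without hippocampus Sox2-GFP replicate C, adjusted p = 0.7025, the ends of the range over 21 alternatives) and Dcx by 2.36 (SE 1.46, adjusted p = 0.604).

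Of the genes with the largest falls in SVZ cells, Tmem72 was 1650-fold lower (adjusted p = 0.019) and well above background on 1 SVZ array. Ttr was 724-fold lower (-3.86 ± 1.56 against 5.64 ± 0.73, adjusted p = 0.0167). Slc4a10, a bicarbonate transporter gene, was 335.5-fold lower (adjusted p = 0.0107), and Cd59b, a complement inhibitor gene, 264-fold (adjusted p = 0.00842). Abca4, a lipid transporter gene, was 246-fold lower (adjusted p = 0.0176), Sulf1 215-fold (adjusted p = 0.0117) and Slc6a20a, a proline transporter gene, 143-fold (adjusted p = 0.0169). Slc4a10 and Sulf1 were well above background on 2 SVZ arrays, and Cd59b, Abca4 and Slc6a20a on 1. The call of Tmem72 ended for 4 of the 6 arrays when 1 was left out (adjusted p from 0.0543 to 0.0816). Those of Ttr, Abca4 and Slc6a20a ended for 3 of the 6. Leaving out SVZ replicate A moved the fold to 3069 for Tmem72, 1349 for Ttr and 397 for Abca4, leaving out SVZ B to 115 for Sulf1, and leaving out SVZ C to 200.7 for Slc4a10 and 333 for Sulf1. Without hippocampus Sox2-GFP B it was 529.9 for Slc4a10 and 231 for Slc6a20a. Without hippocampus Sox2-GFP C it was 119 for Abca4, 207.5 for Slc4a10, 156 for Cd59b, 140.3 for Sulf1 and 75.4 for Slc6a20a. Lmx1a, a LIM homeobox transcription factor, was at least 43.4-fold lower (adjusted p = 0.00116), and Rab11fip1, a vesicle traffic gene, at least 85.8-fold (adjusted p = 0.019). Their smallest log2 differences over the alternatives were -2.54 and -3.61, less than these bounds. The call of Rab11fip1 ended for 3 of the 6 arrays when 1 was left out. Only 6 named genes rose in SVZ cells. Crym, which encodes a thyroid hormone binding protein, was 50.3-fold higher (adjusted p = 0.0296; 88.98-fold without hippocampus Sox2-GFP B) and well above background on 2 hippocampal arrays. Spink10, a protease inhibitor gene, was at least 19.2-fold higher (adjusted p = 0.00237), Anln 32.5-fold (adjusted p = 0.00751) and Meis1, a homeobox gene of the striatal lineage, 17.1-fold (adjusted p = 0.0153). The smallest log2 difference of Spink10 over its alternatives was 2.03, less than its bound. Enox1 was 16.2-fold higher (adjusted p = 0.00874) and the DNA glycosylase gene Neil3 4.88-fold (adjusted p = 0.0487).

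Of 14 choroid plexus genes, 7 fell in SVZ cells and 0 rose (13 fell adjusted over the list alone). The mean was -4.67 ± 2.66 (SD over genes; camera adjusted p = 8.68e-23; 0.146 with an estimated correlation), -5.84 with slide as a block and -5.90 within slide 3. Sostdc1, a secreted BMP and Wnt antagonist gene, was 59.3-fold lower (-4.03 ± 0.31 against 1.86 ± 1.12, adjusted p = 0.00842; 39.3-fold without hippocampus Sox2-GFP C). None of 19 ependymal genes passed (4 fell adjusted over the list alone), while their mean of -1.53 passed camera (adjusted p = 6.15e-06; 0.248 with an estimated correlation). The ependymal mean was -0.81 with slide as a block and -0.73 within slide 3, and Foxj1 differed by -4.11 (SE 0.72, adjusted p = 0.0678). The myelin list did not pass (mean 0.89, camera adjusted p = 0.1575), and 1 of its 18 members fell (1 fell and 2 rose adjusted over the list alone). That gene was Enpp2 (19.6-fold, 1.83 ± 0.47 against 6.12 ± 0.55, adjusted p = 0.00842), which encodes autotaxin and is abundant in the choroid plexus as well as in oligodendrocytes. Of 26 dissociation and stress response genes none passed (1 fell adjusted over the list alone), with a mean of -0.89 (camera adjusted p = 0.00014; 0.221 with an estimated correlation), -0.98 with slide as a block and -0.92 within slide 3. Atf3 had the smallest p of them (-3.65, SE 0.80, adjusted p = 0.142). The mean of 17 glycolysis genes was -0.52, with 0 members called, also adjusted over the list alone (camera adjusted p = 0.0392; 0.37 with an estimated correlation), -0.31 with slide as a block and -0.40 within slide 3, and Pgk1 differed by -2.96 (adjusted p = 0.27).

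Lists that were higher in SVZ than in hippocampus Sox2-GFP cells had called members only in the ventral factors. The 23 G2 and M phase genes had a mean of 1.02 (3 rose adjusted over the list alone; camera adjusted p = 4.63e-05; 0.37 with an estimated correlation), 1.46 with slide as a block and 1.42 within slide 3. Their means on SVZ replicates A, B and C were -0.34, -0.61 and -1.26, against -1.34, -1.56 and -2.36 on hippocampus Sox2-GFP A, B and C. Top2a, a topoisomerase of dividing cells, differed by 3.09 (SE 0.63, adjusted p = 0.1145). The 27 immature neuron genes had a mean of 1.25 (0 adjusted over the list alone; camera adjusted p = 0.00014; 0.37 with an estimated correlation), 2.05 with slide as a block, 1.85 within slide 3 and 0.81 without hippocampus Sox2-GFP replicate C (adjusted p = 0.000528), and Stmn1 differed by 3.90 (SE 0.90, adjusted p = 0.159). SVZ replicate C, at -1.37, was not higher than hippocampus Sox2-GFP A and B (-1.06 and -1.27), while SVZ A and B stood at 0.17 and 0.12 and hippocampus Sox2-GFP C at -2.48. The 10 GABAergic neuron genes had a mean of 1.099 (1 rose adjusted over the list alone; camera adjusted p = 0.0392; 0.482 with an estimated correlation), 1.57 with slide as a block and 1.48 within slide 3. SVZ replicate C, at -1.57, was level with hippocampus Sox2-GFP A and B (-1.40 and -1.58), while SVZ A and B stood at -0.24 and -0.28 and hippocampus Sox2-GFP C at -2.41. Gad2, which encodes a GABA-synthesizing enzyme, differed by 4.48 (SE 1.102, adjusted p = 0.189). Of 17 ventral telencephalic transcription factors, Meis1 rose (1 also adjusted over the list alone), with a mean of 0.82 (camera adjusted p = 0.0276; 0.37 with an estimated correlation), 1.34 with slide as a block, 1.27 within slide 3 and 0.54 without hippocampus Sox2-GFP replicate C (adjusted p = 0.0405). In this list too SVZ replicate C (-2.16) was level with hippocampus Sox2-GFP A and B (-2.22 and -2.16), and SVZ A and B stood at -1.41 and -1.38.

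The 25 astrocyte genes had a mean of 1.21 in the same direction, with 0 called, also adjusted over the list alone (camera adjusted p = 0.00064; 0.531 with an estimated correlation). It was 3.08 with slide as a block and 3.11 within slide 3, and 0.37 (adjusted p = 0.00579; 4.39e-08 to 0.531 over its alternatives) without hippocampus Sox2-GFP replicate C, whose astrocyte values were low. The means on SVZ A and B (2.95 and 3.31) were close to those on hippocampus Sox2-GFP A and B (2.99 and 3.11). SVZ C stood higher, at 3.995, and hippocampus Sox2-GFP C lower, at 0.54. Glul, the glutamine synthetase gene, differed by 1.12 (SE 0.42, adjusted p = 0.393). The 20 histone and chromatin regulators had a mean of 0.59 (0 adjusted over the list alone; camera adjusted p = 0.00913; 0.221 with an estimated correlation), 1.16 with slide as a block, 1.11 within slide 3 and 0.35 without replicate C (adjusted p = 0.00421), with Bcl11b at 1.17 (adjusted p = 0.495). Their mean on SVZ C (-0.07) was close to those on hippocampus Sox2-GFP A and B (-0.08 and -0.18). The 18 cholesterol synthesis genes had a mean of 0.56 (0 adjusted over the list alone; camera adjusted p = 0.0276; 0.221 with an estimated correlation), 0.75 with slide as a block and 0.72 within slide 3, with Dhcr7 at 1.71 (adjusted p = 0.28).

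**Figure D3:**
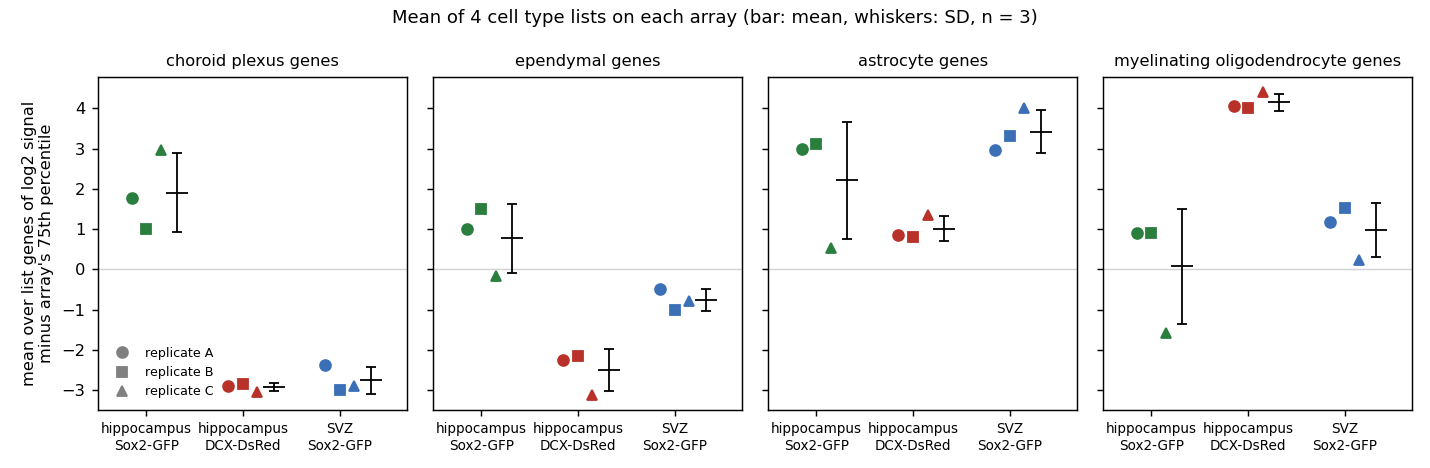
Mean over the measured genes of 4 cell type lists of the log2 signal minus the array's 75th percentile (vertical axis) on each array of the 3 groups (horizontal axis), with marker shape for the replicate letter and bar and whiskers for mean and SD of 3 arrays. Hippocampus Sox2-GFP replicate C has the highest choroid plexus mean (2.95) and the lowest myelin mean (-1.57) and astrocyte mean (0.54) of the 9 arrays.

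The other lists did not pass camera between the regions. Igf2 fell among 19 IGF system genes (3 fell adjusted over the list alone, camera adjusted p = 0.186) and 25 imprinted genes (2 fell adjusted over the list alone, camera adjusted p = 0.294, mean -0.34 and median 0.08). Bad fell (5.97-fold, adjusted p = 0.0325) among 19 apoptosis genes (1 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.932, mean 0.19 and median -0.03). No member passed in the rest, for which limma gave 2690 genes at an unadjusted p under 0.05 over all genes. Lower in SVZ cells among the members with the smallest p were Bmp4 of the precursor and BMP lists (-3.91, adjusted p = 0.1445), Vtn (-4.21, adjusted p = 0.0558), Ogn (-3.62, adjusted p = 0.0659), Etfa (-2.12, adjusted p = 0.0603), Alas2 (-1.01, adjusted p = 0.471) and Cx3cr1 (-0.78, adjusted p = 0.412). Higher were Notch1 (1.95, adjusted p = 0.463), Gria1 (3.51, adjusted p = 0.427), Uhrf1 (1.63, adjusted p = 0.399), Dner (1.95, adjusted p = 0.398), Tcf7l1 (2.37, adjusted p = 0.263), Cdon (1.09, adjusted p = 0.416), Elovl2 (0.93, adjusted p = 0.342) and Ephb2 (3.003, adjusted p = 0.31). Tcf7l1 turned to -0.40 (adjusted p = 0.85; 0.126 to 0.85 over its 21 alternatives) with the mean of its probes.

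Camera adjusted p-values of those lists were 0.321 for neural stem and progenitor, 0.0625 for mature neuron and synapse, 0.607 for oligodendrocyte precursor, 0.833 for microglia and 0.2285 for endothelial and mural genes. They were 0.0718 for meningeal fibroblast, 0.822 for blood cell, 0.463 for S phase, 0.742 for Notch, 0.486 for Wnt, 0.0625 for BMP and TGF beta, 0.2 for hedgehog and 0.186 for dorsal telencephalic genes. They were 0.2955 for fatty acid synthesis, 0.2 for fatty acid oxidation and 0.152 for axon guidance and migration genes. The microglia list had a mean of -0.01 and a median of 0.01. The fit with slide as a block called 3 lists that the other had not, neural stem and progenitor (mean 1.52, adjusted p = 0.0449), myelin (2.55, adjusted p = 0.00575) and meningeal genes (-1.10, adjusted p = 0.0158). These 3 rest on hippocampus Sox2-GFP replicate C: without it their means were -0.12 (adjusted p = 0.893), 0.07 (adjusted p = 0.319) and -0.55 (adjusted p = 0.0924), while the endothelial and mural list passed (-0.78, adjusted p = 0.0288). Adjusted over the list alone, 1 gene fell in each of the oligodendrocyte precursor, endothelial and mural, meningeal, BMP and TGF beta, and fatty acid oxidation lists.

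Of the 19 called genes named for the regions, Igf2, Spink10 and Lmx1a kept an adjusted p under 0.05 in each alternative that tested them. Igf2 was tested in 21 alternatives, and Spink10 and Lmx1a in 20. In the fit with slide as a block, 18 of the 19 passed, all in the same direction, and Neil3 did not (adjusted p = 0.0578; 0.0149 to 0.165 over its 21 alternatives). For 11 genes the call ended when 1 array was left out (adjusted p from 0.0509 to 0.165), and Neil3 lost it whichever of the 6 arrays was left out. Of the 16 of these genes with a fold and not a bound, 9 had it moved by over 1.5 times without 1 array, up to 2.07 times for Abca4 without hippocampus Sox2-GFP C. Over all alternatives some moved further. The log2 difference shrank to -4.42 for Abca4 and -4.94 for Slc6a20a, against -7.94 and -7.16 in the main fit. The count of 99 was 25, 94 and 97 without hippocampus Sox2-GFP replicates A, B and C, 62, 59 and 77 without SVZ replicates A, B and C, and 8 when only the 6 arrays of these groups were fitted. With slide as a block 6 of the 11 called lists passed, the choroid plexus, ependymal, immature neuron, astrocyte, G2 and M phase, and stress lists. Of the 11 called lists, 6 lost their call without 1 array (camera adjusted p from 0.0505 to 0.173): the GABAergic, glycolysis, cholesterol and ventral lists without at least 2 of the arrays in turn, histone and chromatin regulators without SVZ B (0.1232) and astrocyte genes without SVZ C (0.0505).

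Of the genes called higher in hippocampus Sox2-GFP cells, 434 against DCX-DsRed and 88 against SVZ cells, 70 were shared, and of those called lower, 356 and 11, 5 were shared. Both comparisons use the same 3 hippocampus Sox2-GFP arrays. In 20 simulations of unchanged groups the overlap was 0 in each direction. Hardly any gene is called in unchanged groups, so this had to come out near 0 and sets no reference. Independent lists of these lengths would share 1.53 and 0.16 genes, a figure that leaves out the shared arrays. Part of the overlap may come from the shared arrays, which are too few to split. The 5 were Anln, Meis1, Enox1 and 2 transcripts with clone names, singled out because they are few. Of the 70, Igf2, Ttr, Tmem72, Sulf1 and Bad were named in both comparisons.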

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

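Of the tests below, those of meningeal cells, of the slides for the choroid plexus and myelin genes, and of the low values of hippocampus Sox2-GFP replicate C were chosen after the result was seen.

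Igf2 and the choroid plexus list were higher in hippocampus Sox2-GFP cells than in both other groups. Of 14 list members, 11 were called against DCX-DsRed and 7 against SVZ cells. Camera with an estimated correlation called the list in neither comparison (adjusted p = 0.122 and 0.146). On replicates A, B and C Ttr, an abundant transcript of the choroid plexus, stood at 5.42, 5.05 and 6.45, against -5.04, -4.80 and -1.17 in DCX-DsRed and -2.06, -4.69 and -4.82 in SVZ cells. Meningeal cells as a source of Igf2 stay open. Their list had a median of 0.36 (SD 1.34 over genes) above the nearer other group. It passed camera against DCX-DsRed (adjusted p = 0.0445, 0.465 with an estimated correlation) but not against SVZ cells (0.0718). That median cannot decide, since Igf2 was near background in the other groups and can rise from there by a larger fold than genes with signal. A difference between slides stays open too. The choroid plexus median of 5.57 (SD 2.92) with slide as a block rests on replicate C, the only array of its group on a slide with another group. Choroid plexus epithelial cells among the sorted cells are a candidate source: of a second list of 24 of their genes, chosen before its values were seen, 15 (62.5%) were over 2-fold higher in hippocampus Sox2-GFP cells than in each other group, against 7.84% of all genes, with 7 called higher than in DCX-DsRed and 2 higher than in SVZ cells. Of the 24 genes, 21 were well above background on all 3 DCX-DsRed arrays and 22 on all 3 SVZ arrays, 0 stand in a list fixed before the data were examined, and Ecrg4 and Slc2a12 are also among the named genes. The GFP gate would remove such cells if they carry no GFP, which was not tested, and neither was expression of these genes by the hippocampal Sox2-GFP cells themselves, so both stay open.

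Myelin genes were higher in DCX-DsRed than in hippocampus Sox2-GFP cells, with 11 of 18 called: Mog (adjusted p = 0.0208) stood at 3.88, 4.44 and 4.78 on DCX-DsRed, 0.08, -0.31 and -3.32 on hippocampus Sox2-GFP and 1.40, 1.36 and -0.56 on SVZ replicates A, B and C, and the abundant Mbp, which did not pass (adjusted p = 0.129), at 5.08, 5.09 and 5.52, 1.97, 2.56 and -2.48, and 1.55, 3.12 and -0.48. The low values of hippocampus Sox2-GFP replicate C do not account for this, since the myelin median without that array was -3.30 (SD 1.74 over genes). DCX-DsRed exceeded SVZ cells in 18 of 18 genes within slide 1 (median 2.90, SD 0.87) and within slide 3 (3.66, SD 1.06), with a median of 2.86 (SD 0.86) for the smaller of both per gene. This argues against a difference between slides for the excess over SVZ cells only. Against hippocampus Sox2-GFP cells a difference between slides stays open, since their replicates A and B lay on slide 2 with no other group. Oligodendrocytes among the sorted DCX-DsRed cells are a candidate source: of a second list of 20 of their genes, chosen before its values were seen, 19 (95%) were over 2-fold higher in DCX-DsRed cells than in each other group, against 7.71% of all genes, and 8 were called. Of the 20 genes, 19 were well above background on all 3 hippocampus Sox2-GFP arrays and 19 on all 3 SVZ arrays, and 0 stand in a list fixed before the data were examined. The DsRed gate would remove oligodendrocytes that carry no DsRed, which was not tested, and expression of myelin genes by the DCX-DsRed cells themselves was not tested either, so both stay open.

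Hippocampus Sox2-GFP replicate C stood apart from A and B, with lower astrocyte (median -2.75), myelin (-1.94) and neural stem and progenitor genes (-1.31) and higher choroid plexus genes (1.47). An effect of slide 3 common to the groups is argued against: the deviations of the other groups' arrays on slide 3 correlated with its own, across genes, at -0.033 and -0.0377. An effect of slide 2 stays open, since that slide held only replicates A and B and no other group. A larger share of choroid plexus cells in this sort is a candidate explanation: the second choroid plexus list had a median 1.44 higher in replicate C than in the mean of A and B, and 66.7% of its members were higher in C than in both. The labels name no difference between these replicates, so no biological difference from the design was tested, nor was an uneven amplification of the RNA, and Xist also stood apart, at -0.63 against 1.95 and 2.08.

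Each comparison allows 10 splits of its 6 arrays, too few for a share under 0.05. In the hippocampal comparison only the real split, 1 of 10, gave 790 genes (the highest other gave 5) and 15 lists (5). Between the regions the real split, 1 of 10, gave 99 genes (the highest other gave 9), while 2 of 10 splits gave 11 or more lists, with 12 in the highest other, which does not follow the slides.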

How the results depend on the processing

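Of these alternatives, naming genes from accessions only was chosen after the result was seen: it gave 816 and 99 genes and 12 and 10 lists for the hippocampal comparison and the regions. In the hippocampal comparison (790 genes, 15 lists) normexp with quantile normalization gave 1265 genes, array weights 5516, slide as a fixed block 2024 (503 of the 790 among them) and an adjusted p under 0.01 184. For genes that differ between Sox2-GFP cells of the SVZ and of the hippocampus (99 genes, 11 lists) normexp with the 75th percentile gave 160 genes, normexp with quantile normalization 221, probes well above background on 6 arrays 64, the mean of probes 173, every probe as a feature 154, the 6 arrays alone 8, array weights 343, slide as a fixed block 2128 (95 of the 99 among them) and an adjusted p under 0.01 18. The array weights ran from 0.25 for hippocampus Sox2-GFP C to 4.48 for A, and slide as a fixed block leaves replicate C alone to stand for that group. Leaving out 1 array in turn gave 251 to 773 and 25 to 97 genes, and 9 to 14 and 6 to 11 lists. The lists called were 0 and 0 with an estimated correlation and 9 and 4 with fry, and 5 in the hippocampal comparison with slide as a fixed block. A random slide block (856 and 146 genes) had no list test, and every probe as a feature and the stricter thresholds gave counts of genes only. Among named genes and called lists, directions turned for Dcx in the hippocampal comparison (0.32 with array weights), Tcf7l1 between the regions (-0.40 with the mean of its probes), the astrocyte list in the hippocampal comparison (-0.87 with slide as a fixed block, -0.82 within slide 3) and the Notch list there (-0.71 and -0.61). Of the lists not called, the means of neural stem and progenitor (-0.70) and hedgehog genes (-0.50) in the hippocampal comparison and of endothelial and mural (0.42), microglia (0.22), Wnt (0.09) and imprinted genes (0.02) between the regions also turned with slide as a fixed block. Fewer arrays entered the fits with an array left out and that of 6 arrays alone, and for the other settings the cause was not tested. Among the other values of the hippocampal comparison, named genes kept direction and side of the threshold in 1110 cases, no longer passed in 178, passed anew in 25 and moved by more than the spread, with no test, in 44. Lists did so in 258, 72, 0 and 11. Between the regions these counts were 840, 78, 34 and 30 for genes and 201, 47, 0 and 5 for lists. Signal over background limits 128 and 28 of the called genes to a bound. No pairing of the arrays by replicate letter was seen: 1 of 9 same-letter pairs had deviations correlated over 0.1 (-0.0442 to 0.115), and in 4 of 18 cases the best match in another group carried the same letter. The pair over 0.1, DCX-DsRed A and SVZ A, also shared slide 1. This check therefore cannot tell whether arrays with the same letter were prepared together. The letter as a block gave 489 and 13 genes, with 15 and 11 lists.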

Other observations

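The genes and samples below were singled out after their values were seen, no alternative was run on them except Slc4a10 between the regions, and no test was made of what they mean.

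Of the 70 genes higher in hippocampus Sox2-GFP cells than in both other groups, 4 genes of receptors and a secreted signal are given as single examples, with no list or test of such genes. Prlr, the prolactin receptor gene and a member of the choroid plexus list above, stood at 2.95 ± 1.12 there, 14.98-fold higher than in DCX-DsRed cells (limma, adjusted p = 0.0138) and 15.6-fold higher than in SVZ cells (adjusted p = 0.0369). Lepr, the leptin receptor gene, was 22.9-fold and 26.8-fold higher (adjusted p = 0.0177 and 0.0414), and Fzd4, a Wnt receptor gene, 36.0-fold and 31.4-fold (adjusted p = 0.0073 and 0.0239), well above background on 2 of 3 DCX-DsRed arrays. Sema3b, which encodes a secreted semaphorin, was 98.5-fold and 67.2-fold higher (adjusted p = 0.00248 and 0.00945). All 4 were higher on each hippocampus Sox2-GFP array than on each of the 6 others. As the 4 genes were picked from those called higher in both comparisons, this lack of overlap is no separate support. They were highest on replicate C, at 4.12 for Prlr, 2.29 for Lepr, 1.45 for Fzd4 and 3.87 for Sema3b.

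Of the same 70 genes, Cldn2 and Clic6 are also members of the choroid plexus list, and Slc4a10 is not. That list is short, so this does not set Slc4a10 apart from the choroid plexus pattern. Cldn2, which encodes claudin 2, a pore-forming junction protein, stood at 2.14 ± 0.37 in hippocampus Sox2-GFP, -0.93 ± 0.76 in DCX-DsRed and -2.19 ± 0.08 in SVZ cells (adjusted p = 0.0106 and 0.00892). Clic6, a chloride channel family gene, was 36.7-fold and 12.7-fold higher (adjusted p = 0.00351 and 0.0322), and Slc4a10, the bicarbonate transporter gene lower in the SVZ, was also 49.4-fold higher than in DCX-DsRed cells (adjusted p = 0.0153).

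Genes of the sex chromosomes differed between replicates of a group. Xist, the X inactivation transcript of female cells, read -3.43, -3.47 and 2.18 on DCX-DsRed replicates A, B and C, and the Y-linked gene Uty read -1.63, -1.76 and -6.77. On hippocampus Sox2-GFP replicates A, B and C, Xist read 1.95, 2.08 and -0.63 and Uty -3.18, -2.35 and -1.78, and on the SVZ replicates Xist read 2.27, 3.78 and 2.93 and Uty -5.26, -8.07 and -6.64. None of the 5 sex chromosome genes examined passed in a comparison (adjusted p from 0.227 for Kdm5d upward), with 4212 and 2690 genes at an unadjusted p under 0.05. Xist was higher, and the Y-linked genes Uty and Ddx3y were lower, on each SVZ array than on each hippocampus Sox2-GFP array. The Y-linked genes Eif2s3y and Kdm5d overlapped between these groups. The labels name no sex, so whether the mix of sexes differed between groups as well as replicates was not tested.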
